A study of Mus musculus with 8 samples.

How the data were processed

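DNase-seq was done on 8 libraries of mouse 3134 mammary epithelial cells, from the parental line and from lines with inducible dominant-negative Brg1, Chd4 or Snf2h, each with tetracycline and 48 hours after its removal. Groups were taken from the submitters' labels, and each group has 1 library. The numbers in the sample titles follow the tetracycline state and do not mark replicates.

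The sequences were processed with CASAVA 1.6 and placed on build mm9, per the submitters' processing notes. The hotspot caller, its version and its filters are not given in the sources used here. The authors deposited 1 hotspot list per library. Per the file headers, each hotspot has a highest and a mean tag density, which are a signal (coverage density) scaled by a factor of its library. The target of that scaling is not given in the sources used here. Per the file headers, the deposited lists also hold a score of enrichment (a z-score) that the authors computed per hotspot. They also hold a p-value per hotspot, deposited by the authors. Both are the authors' own values and were used only to describe a list. The p-value was listed as 0 for 13.9% to 44.4% of the hotspots of a list. The mean density exceeded the highest density in 1 hotspot, in DNCHD4 cells without tetracycline.

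Each library's peak densities were checked for a common step, and 100% of them were whole multiples of it within 0.05 tags. A tag was worth a density of 0.179 to 0.586, and peak densities were turned into tags by dividing by that step. If all libraries had been scaled to 1 target, relative depth would range from 1.0 in DNBrg1 cells with tetracycline to 3.27 in DNCHD4 cells with tetracycline. Total depth is unknown. Each deposited list begins just above its own density threshold, so a region absent from a list is not a region without cuts. The hotspots are numbered in genome order with gaps, 5172 to 14747 numbers per list, so hotspots were removed after numbering by a step that is not given in the sources used here. Of the sites called changed by a bound, the share with no number missing at their position in the other list was 83.7% and 75.9% for lower and higher sites in DNBrg1, 98.3% and 79.2% in DNCHD4, 85.3% and 87.4% in DNSnf2h, and 76.6% and 53.8% in the parental line. Over all intervals between listed hotspots, a number was missing in 9.52% and 13.8% in the DNBrg1 lists without and with tetracycline. In the same order the shares were 4.20% and 10.7% in DNCHD4, 14.3% and 9.06% in DNSnf2h, and 12.3% and 18.4% in the parental line. Called sites thus had a number missing more often, apart from lower sites of DNCHD4. Among the named sites absent from a list of their line, 1 site of DNCHD4 cells has a number missing at its position, and is described with its value.

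Hotspots of the libraries of a line were merged into sites where they overlapped by at least 1 bp, and the value of a site in a library was its highest peak density there. The ratio was the value without over the value with tetracycline, and a site was called changed at 2-fold. A site listed in 1 library was set against the lowest density of the other list, which gives a bound. The bound assumes that the other library would have listed any higher density. It fails in clusters of many hotspots, as on chromosome 11 from 3023556 to 3190382 in parental cells with tetracycline, where 44 hotspots had a lowest density of 24.5 against 13.0 in the whole list. Because the scaling target is unknown, counts are given as deposited and with the median ratio of the sites listed in both libraries set to 1. The median moved by over 0.1 on the log2 scale in the parental and DNBrg1 lines only. Intervals on ratios are exact binomial intervals on tags and those on shares are Wilson intervals, both at 95%. Both cover counting error only, since fragments without molecular identifiers are not independent molecules. No interval is given for a bound, because the lowest density of the other list is a cutoff and not a count at the site.

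Overlap shares were counted with bedtools 2.31.1, with at least 1 bp, and compared with 100 random placements within chromosomes. Overlap of changed sites between lines was compared with the product of the list lengths over the number of sites, and with 1000 random lists matched on the highest density of a site in 20 bins. Each line has its own library with tetracycline, so no control library is shared. After the data were seen, 2 backgrounds were added: sites listed in all 3 lines for the overlap of the 3, and, for the share of changed sites that overlap a parental hotspot, sites changed under 2-fold and matched in 20 bins on the highest density of the site in the line. Intervals of median shifts on chromosome 14 are from 1000 bootstrap draws of sites. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The calling step was tested on simulated data for each line, with 200 changed sites among 40101 parental, 36114 DNBrg1, 84480 DNCHD4 and 41657 DNSnf2h sites: 100% of 3-fold and of 4-fold changes were recovered in each line, and 0, 4, 12 and 2 unchanged sites were called. The changed sites were drawn only from sites at least 4 times above the higher of the 2 list thresholds, so recovery at weaker sites was not tested. The simulation holds tag-counting noise alone and not the variation between cultures or digestions.

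Tests, the rule for named sites and a list of other settings were fixed before the data were examined. The rule named, per dominant-negative line, the 3 sites with the largest rise and the 3 with the largest fall among those at least 2-fold changed and not changed 2-fold the same way in parental cells, and the 3 per direction with the largest mean log2 ratio among those changed alike in all 3 lines and not in parental cells. It found 2 sites for a rise in all 3 lines. The other settings were folds of 1.5 and 3, median centring, quantile normalization, mean density, sites listed in both libraries, all sites listed in 1 library, merging across 200 bp, reciprocal overlap of 50%, a common threshold and equal list lengths for the overlap shares, and another background for the overlap of changed sites. After the data were seen, a common threshold for the counts, centring by density, a counting interval that excludes 1, centred sites not changed alike in parental cells, and a local lowest density in regions with at least 10 hotspots within 50 kb were added.

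Gene names, promoter shares, gene lists and sequence motifs were planned for the case of an annotation and genome of build mm9 and are not analysed here. The gene table at hand is on GRCm38, and on 10 of the 20 chromosomes the last hotspot lies beyond its last gene, so its coordinates were not used. The lists hold 19 autosomes and X. Coordinates are those of the authors' files.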

Results

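Accessible chromatin was mapped by DNase-seq, in which DNase I cuts open chromatin in isolated nuclei and the released fragments are sequenced. The cells were 3134 cells, a mouse mammary epithelial line, and 3 derived lines that each carry a catalytically impaired, dominant-negative form of a chromatin remodeling ATPase under tetracycline control. Brg1 is an ATPase of the SWI/SNF complexes, Chd4 is an ATPase of the NuRD complex, and Snf2h is an ATPase of the ISWI complexes. Removal of tetracycline for 48 hours induced the dominant-negative protein. Each of the 4 lines was measured once with and once without tetracycline, which gave 8 libraries and 1 library per group, so no difference below has a replicate check and no p-value is given. The parental line, measured the same way, is the background for tetracycline removal.

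Each library was represented by a list of hotspots, which are regions enriched in DNase I cuts, on mouse build mm9. The parental line had 35083 hotspots with and 35071 without tetracycline. The DNBrg1 line had 29379 and 30423, the DNCHD4 line 48888 and 78093, and the DNSnf2h line 24890 and 33793. The lists had different density thresholds: the lowest peak density was 13.0 with and 10.0 without tetracycline in the parental line, 16.4 and 9.19 in DNBrg1, 8.05 and 5.09 in DNCHD4, and 8.03 and 8.06 in DNSnf2h. Within a library all peak densities were whole multiples of 1 step, so the lowest hotspot of a list corresponded to 26 to 45 tags and the median hotspot to 56 to 126 tags. The counting error of the median hotspot was therefore 8.89% to 13.4% of its density. Merging the 8 lists gave 99999 sites, of which 12592 were listed in all 8 libraries and 51353 in 1 library. Of the sites listed in 1 library, 31957 (62.2%) came from DNCHD4 cells without tetracycline.

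The 4 libraries kept with tetracycline, in which no dominant-negative protein was induced, showed how far the lines differed on their own. The parental and DNCHD4 lines were the closest pair, with 98.5% of parental hotspots overlapping a DNCHD4 hotspot (95% interval 98.4 to 98.6) and a Spearman correlation of peak density of 0.94 across 33551 shared sites. After the median ratio of shared sites was set to 1, 1.06% of the sites of this pair differed at least 2-fold. The same share was 8.57% between the parental and DNBrg1 lines and 25.2% between the parental and DNSnf2h lines. At shared sites, density in the DNSnf2h library stood at a median log2 ratio of -1.51 to the parental, -1.60 to the DNBrg1 and -1.63 to the DNCHD4 library. On chromosomes 14 and 18, both DNBrg1 libraries had a median density shift below 0, relative to the libraries of the other lines, in 16 of 18 windows of 10 Mb. The other 2 windows were those of chromosome 14 from 100 Mb on, at a median shift of -0.12 with and 0.11 without tetracycline. Sites are not independent replicates, so these correlations and shares describe the libraries only. Intervals on shares are Wilson intervals, and all intervals cover counting error alone.

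**Figure D1:**
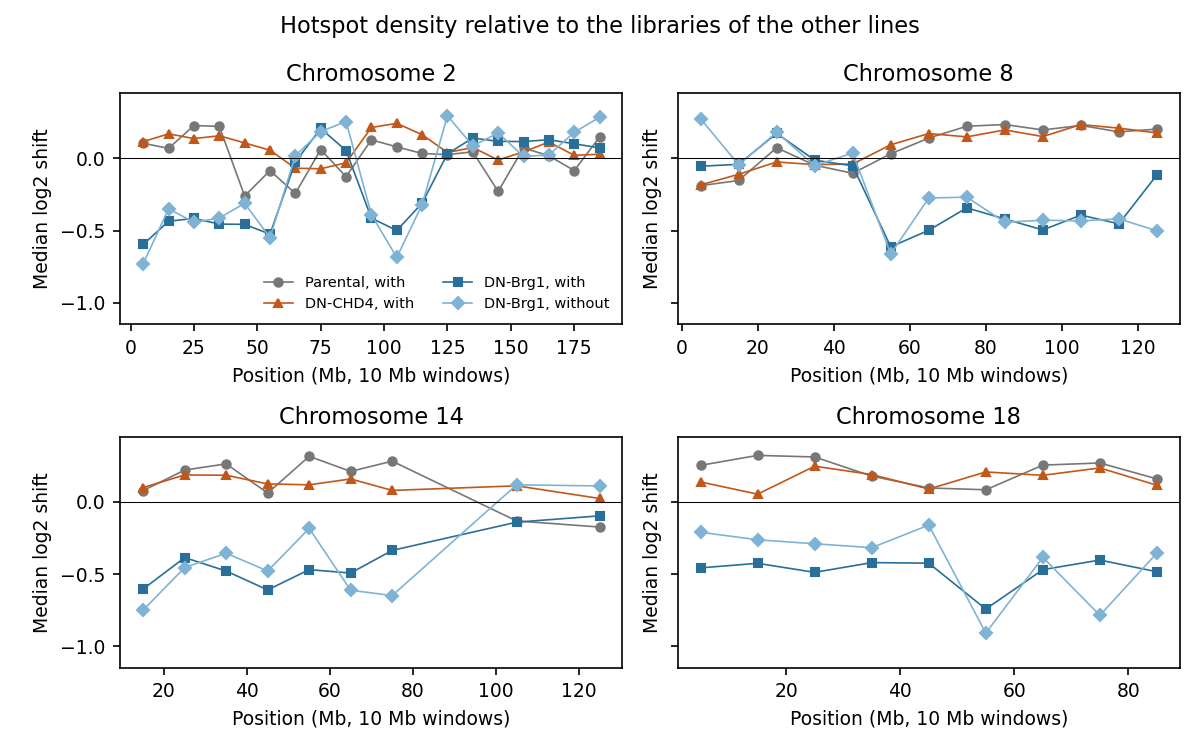
Median log2 shift of peak density, relative to the libraries of the other lines, in windows of 10 Mb along chromosomes 2, 8, 14 and 18, for the parental and DNCHD4 libraries with tetracycline and both DNBrg1 libraries. Both DNBrg1 libraries stand below 0 in 16 of the 18 windows of chromosomes 14 and 18, all but those of chromosome 14 from 100 Mb on, and change level along chromosomes 2 and 8.

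In parental cells most hotspots were listed in both tetracycline states, and densities as deposited were lower without tetracycline at most shared sites. Of the hotspots with tetracycline, 84.3% (83.9 to 84.7) overlapped a hotspot without tetracycline, and 85.0% (84.7 to 85.4) did so in the other direction, against 2.05% for randomly placed hotspots. Peak density at the 29355 sites listed in both libraries had a median log2 ratio, without over with tetracycline, of -0.40 (SD 0.46 across sites). As deposited, 273 sites were at least 2-fold higher and 3886 at least 2-fold lower without tetracycline, so 6.56% of the changed sites were higher. With the median ratio set to 1, the counts were 1043 higher and 926 lower, and 53.0% were higher. The direction of the parental change therefore depended on the scaling of the libraries, and 4.91% of the 40101 sites differed at least 2-fold after it.

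**Figure D2:**
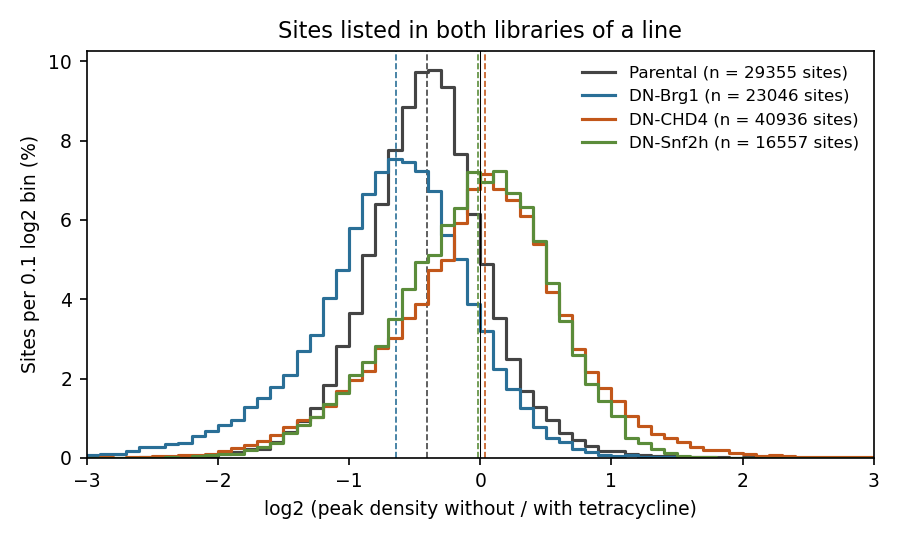
Distribution across sites of the log2 ratio of peak density without over with tetracycline, as the percent of sites per bin, for sites listed in both libraries of each line; dashed lines mark the medians. The medians are -0.40 in the parental line, -0.64 in DNBrg1, 0.03 in DNCHD4 and -0.02 in DNSnf2h.

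Cells with dominant-negative Brg1 lost density at far more sites than they gained it. As deposited, 10620 of 36114 sites were at least 2-fold lower and 105 at least 2-fold higher, so 0.979% of the changed sites were higher. A site listed in 1 library counted as lower from a density of 18.4 with tetracycline, but as higher only from 32.8 without it. Of the calls, 4621 lower and 58 higher sites were listed in 1 library. Among sites listed in both libraries, 5999 were lower and 47 higher. The median log2 ratio was -0.64 (SD 0.61), and with this shift removed 3263 sites were lower and 1059 higher, of which 24.5% were higher. Of the centred changes, 2938 lower and 883 higher sites were not changed at least 2-fold in the same direction in parental cells. Hotspots with tetracycline overlapped a hotspot without it in 80.0% of cases (79.5 to 80.4), and 76.4% (75.9 to 76.8) overlapped in the other direction, against at most 1.82% in 100 random placements. At a common density threshold of 16.4, 5934 sites were lower and 105 higher.

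The sites with the greatest fall in DNBrg1 cells were hotspots in the other lines as well. A site on chromosome 2 from 167419686 to 167420675 had a peak density of 183 with tetracycline and was not listed without it, at least 19.97-fold lower. The library without tetracycline listed 8 hotspots within 50 kb of it, the lowest at 19.9. In parental cells the site had 295 with and 155 without tetracycline, a log2 ratio of -0.93. On chromosome 15 from 77709938 to 77710837, density was 158 with tetracycline and none was listed without it, at least 17.2-fold lower. Parental cells had 178 and 91.6 there. On chromosome 1 from 196503834 to 196504802 the value was 133 with tetracycline and at least 14.5-fold lower without it. The parental values at that site were 104 and 62.0. Within 50 kb, the DNBrg1 library without tetracycline listed 6 hotspots near the chromosome 15 site, the lowest at 26.0. Near the chromosome 1 site it listed 5, the lowest at 13.5. A fall measured against such local values would be smaller than the bounds. Relative to the median shift of the line, the log2 bounds at these 3 sites were -3.67, -3.46 and -3.21. As deposited, the sites on chromosomes 2, 15 and 1 fell in every line. In this order the log2 ratios were -0.93, -0.96 and -0.75 in parental cells, -0.83, -1.01 and -0.68 in DNCHD4, and -1.04, -0.89 and -1.05 in DNSnf2h. The 3 sites that the bound from the list's lowest value ranked highest for a rise all lay on chromosome 11, starting at 3078792, 3034525 and 3086443, with densities of 81.1, 80.6 and 75.01 without tetracycline and no hotspot with it. They lie in a dense cluster of hotspots in which the DNBrg1 library with tetracycline listed nothing under 63.9, so that bound does not apply there, a 2-fold rise is not shown and no fold is given. Of the DNBrg1 sites that were lower after centring, 94.99% (94.2 to 95.7) overlapped a parental hotspot, as did 90.05% (88.0 to 91.8) of the higher and 81.9% (81.5 to 82.3) of the other sites. Changed sites were stronger than the others. Other sites matched on density in this line overlapped a parental hotspot in 97.8% of cases for the lower and 93.2% for the higher sites. The excess over 81.9% thus went with density, and changed sites overlapped less often than matched ones.

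**Figure D3:**
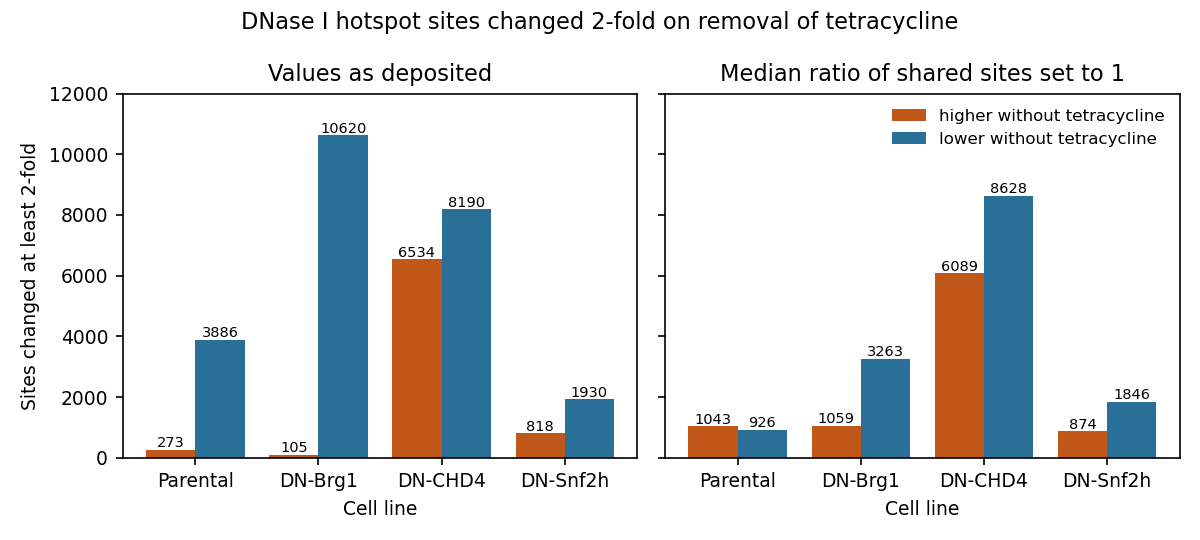
Number of sites at least 2-fold higher (orange) or lower (blue) without than with tetracycline in each line, 1 library per group, with values as deposited on the left and with the median ratio of shared sites set to 1 on the right. Centring turns the parental counts from 273 higher and 3886 lower to 1043 and 926, while DNBrg1 keeps more lower than higher sites on both scales (10620 against 105, and 3263 against 1059).

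Cells with dominant-negative Chd4 both gained and lost hotspots, and their list without tetracycline was 1.597 times as long as the list with it. At least 2-fold changes were found at 6534 higher and 8190 lower sites of 84480, and centring gave 6089 higher and 8628 lower sites because the median log2 ratio was 0.03 (SD 0.68). Of the hotspots with tetracycline, 85.0% (84.7 to 85.3) overlapped a hotspot without it, but 53.6% (53.3 to 54.0) of those without tetracycline overlapped one with it. At a common threshold of 8.05 the lists held 48888 and 58759 hotspots, a ratio of 1.202, and the lower sites numbered 4636, fewer than the 6534 higher ones. Lower sites outnumbered higher ones under 9 of the 14 settings tried and higher sites under 5, so neither direction prevailed independently of the processing.

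The greatest rises in DNCHD4 cells were at sites nearly absent elsewhere. On chromosome 1 from 191017978 to 191019153 the density without tetracycline was 149, and no other library listed the site. That is 18.6-fold above the lowest density listed with tetracycline. The numbering of the list with tetracycline has 1 number missing at that position, so 1 numbered hotspot near it is not in that list. The site itself may have been removed, so 18.6-fold is not a firm bound. Within 50 kb that list held 1 hotspot, at 47.6, and against it the rise would be smaller. On chromosome 6 from 137095292 to 137096097 the density was 115, at least 14.3-fold higher, and again no other library listed it. Within 50 kb the list with tetracycline held 7 hotspots, the lowest at 10.7. On chromosome 5 from 109981964 to 109982985 the density was 135, at least 16.7-fold higher. The list with tetracycline held 5 hotspots within 50 kb of this site, the lowest at 8.23. The libraries of parental and DNBrg1 cells without tetracycline listed the site at 15.4 and 15.6. The greatest falls included chromosome 7 from 152503292 to 152504015, at 65.7 with tetracycline and at least 12.9-fold lower without it. Parental cells had 67.3 and 37.6 there. On chromosome 16 from 10574836 to 10575623 a density of 64.4 fell at least 12.6-fold, against 32.6 and 20.1 in parental cells. Within 50 kb, the DNCHD4 library without tetracycline listed 8 hotspots at each of these 2 sites, the lowest at 18.4 and 12.9. DNSnf2h had log2 bounds of -1.04 and -1.03 at these 2 sites, and DNBrg1 one of -2.54 at the former. The DNSnf2h library without tetracycline listed nothing under 11.7 and 13.3 within 50 kb, against 16.6 and 16.4 at the sites with tetracycline. A fall measured against such local values would be smaller than the bounds. A site on chromosome 11 from 3030593 to 3031102 was listed at 58.9 with tetracycline and not without it, but it lies in the dense cluster described for DNBrg1, where this library listed nothing under 40.5. Of the DNCHD4 sites that were higher after centring, 42.4% (41.1 to 43.6) overlapped a parental hotspot, against 59.6% (58.5 to 60.6) of the lower and 44.4% (44.0 to 44.8) of the other sites. Other sites matched on density in this line overlapped a parental hotspot in 90.2% of cases for the higher and 61.9% for the lower sites.

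In cells with dominant-negative Snf2h, more of the changed sites were lower than higher under 12 of 14 settings, and the reverse under 2. There were 818 higher and 1930 lower sites of 41657 as deposited, and 874 and 1846 after centring, with a median log2 ratio of -0.02 (SD 0.58). The changed share was 6.53% after centring, beside 4.91% in parental cells, 12.0% in DNBrg1 and 17.4% in DNCHD4, and 6.60% as deposited, beside 10.4%, 29.7% and 17.4%. The order of DNSnf2h and parental cells, and of DNBrg1 and DNCHD4, therefore turned with the scaling. Of the hotspots with tetracycline, 67.4% (66.8 to 68.0) overlapped a hotspot without it, and 49.7% (49.2 to 50.2) overlapped in the other direction. Hotspots of this line were mostly weak: without tetracycline 10.7% had a density of at least 4 times the lowest of the list, against 36.4% in DNCHD4, and a site listed once can be called changed only where it stands at least 2-fold above the lowest density of the other list.

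In DNSnf2h cells, on chromosome 19 from 16942776 to 16943645 density rose from 8.78 to 37.3, which is 4.25-fold (3.07 to 5.98), beside 38.4 and 60.2 in parental cells. The site rose 3.02-fold in DNCHD4 and went from 107 to 74.0 in DNBrg1, a log2 ratio of -0.54 as deposited and 0.11 after centring. After centring, the parental log2 ratio there was 1.05, so the site then counts as higher in parental cells as well. On chromosome 16 from 16911818 to 16912690 density was 34.3 without tetracycline, 4.27-fold above the lowest density listed with it, beside 52.1 and 62.8 in parental cells. The library with tetracycline listed 2 hotspots within 50 kb, the lowest at 27.8. Against that local value a 2-fold rise is not shown. As deposited, the site went from 48.0 to 28.6 in DNBrg1 and from 59.9 to 88.7 in DNCHD4. A further site on chromosome 11, from 3036445 to 3037775, had 64.9 without tetracycline and none listed with it, again in the dense cluster. Density fell on chromosome 8 from 94139208 to 94140615, from 50.4 to 11.3, which is 4.47-fold (3.34 to 6.07), beside 79.4 and 42.2 in parental cells, 3.36-fold lower in DNCHD4 and at least 2.42-fold lower in DNBrg1. On chromosome 10 from 106212303 to 106213152 it was 37.0 with tetracycline and at least 4.59-fold lower without it, beside 18.6 and 11.1 in parental cells. On chromosome 2 from 131909853 to 131911107 it was 35.9 with tetracycline and at least 4.45-fold lower without it. Parental cells had 44.6 and 26.5 there, and density in DNCHD4 fell 3.96-fold. Of the sites lower after centring, 97.8% (96.99 to 98.4) overlapped a parental hotspot, as did 93.9% (92.1 to 95.3) of the higher and 57.4% (56.9 to 57.9) of the other sites. Other sites matched on density in this line did so in 99.2% of cases for the lower and 98.5% for the higher sites. Here too the excess over 57.4% went with density, and changed sites overlapped less often than matched ones.

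Sites lower without tetracycline overlapped between the dominant-negative lines more than independent lists would. As deposited, DNBrg1 and DNCHD4 shared 2075 lower sites against 840 for independent lists, DNBrg1 and DNSnf2h 958 against 195, and DNCHD4 and DNSnf2h 978 against 153. Shared higher sites numbered 33 against 5.92, 14 against 0.709 and 160 against 50.7. These counts take all merged sites as the background, and among sites listed in both lines of a pair the expected counts are 936, 497 and 287 for lower and 5.66, 2.41 and 30.7 for higher sites. Random lists matched on density shared on average 1170, 584 and 207 lower and 7.67, 2.61 and 70.3 higher sites. After centring, and among sites listed in both lines of a pair, the shared lower sites were 929 against 303, 442 against 168 and 991 against 288, or 3.07 (2.88 to 3.27), 2.63 (2.39 to 2.89) and 3.44 (3.22 to 3.66) times the count of independent lists. The highest overlaps among 1000 random lists matched on density were 353, 230 and 338. On this scale and background each line overlapped the parental change by a larger factor, 4.69 (4.18 to 5.23) for DNBrg1, 4.75 (4.36 to 5.16) for DNCHD4 and 5.59 (4.96 to 6.27) for DNSnf2h, although parental cells hold no dominant-negative protein. As deposited, on the same background, the factors were 2.21 to 3.61 with the parental line and 1.93 to 3.41 between dominant-negative lines, so the order did not hold for every pair. Across the 12592 sites listed in all 8 libraries, log2 ratios correlated most between DNCHD4 and DNSnf2h (Pearson 0.59). DNBrg1 stood at 0.49 with DNCHD4 and 0.32 with DNSnf2h. With the parental line the values were 0.51 for DNBrg1, 0.53 for DNCHD4 and 0.30 for DNSnf2h. The order of the pairs thus also depended on the measure. Opposite changes were rarer than for independent lists in each pair of dominant-negative lines, from 0.06 to 0.46 times that count.

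In all 3 dominant-negative lines together, 553 sites were lower as deposited, and 206 of them were not at least 2-fold lower in parental cells. Independent lists would give 56.3 among the 20841 sites listed in all 3 lines (15.9 over all merged sites). After centring 282 were lower, against 20.3 among the sites listed in all 3 lines. Of the 282, 190 were not at least 2-fold lower in parental cells. Among the sites lower as deposited in each of the 3 lines but under 2-fold in parental cells, chromosome 16 from 18860069 to 18860861 had log2 ratios of -3.73 in DNBrg1 (a bound), -1.56 in DNCHD4 and -1.41 in DNSnf2h, against -0.80 in parental cells. Chromosome 12 from 8437492 to 8439534 had -3.49 (a bound), -1.46 and -1.36, against -0.73, and the chromosome 7 site named for DNCHD4 had bounds of -2.54, -3.69 and -1.04, against -0.84. Within 50 kb of the chromosome 7 site, the 3 libraries without tetracycline listed nothing under 19.9, 18.4 and 11.7. Near the chromosome 16 site, the DNBrg1 library without tetracycline listed nothing under 40.3. The bounds use the lower value of the whole list. As deposited 11 sites were higher in all 3 lines, of which 2 were under 2-fold in parental cells. After centring 48 were higher, of which 8 were not at least 2-fold higher in parental cells. The first of the 2, on chromosome 17 from 39979698 to 39985946, held the highest single density of the 8 libraries and rose 2.90-fold in DNBrg1 (1802 to 5222), 2.56-fold in DNCHD4 (1832 to 4689) and 2.57-fold in DNSnf2h (567 to 1459), but also 1.94-fold in parental cells (2126 to 4129). The second, on chromosome 6 from 3151116 to 3151896, rose 2.49-fold, 2.34-fold and 2.06-fold, beside 1.66-fold in parental cells. After centring, the parental log2 ratios of these sites were 1.36 and 1.13, so both then count as higher in parental cells as well.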

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

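For the longer DNCHD4 list, the tests of depth and of the threshold as the whole cause were chosen after the result was seen, and the first test of the threshold before. The differences between lines in this part come from 1 library per group and were not tested.

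At each list's own threshold, the list of hotspots was longer without tetracycline in 3 lines and slightly shorter in the parental line. The list without tetracycline was 1.04 times as long as the list with it in DNBrg1, 1.597 times in DNCHD4 and 1.36 times in DNSnf2h, against 35071 and 35083 hotspots in the parental line. At a common threshold the ratios in this order were 0.643, 1.202, 1.387 and 0.828 with densities as deposited, and 0.938, 1.18, 1.387 and 1.014 with centred ones. The DNBrg1 list was then the shorter one without tetracycline on both scales, while the parental direction turned with the scaling. After centring, higher sites made up 24.5% of the changed sites in DNBrg1, 41.4% in DNCHD4 and 32.1% in DNSnf2h, against 53.0% in the parental line. The median log2 ratio of shared sites was 0.033 in DNCHD4 and -0.40 in the parental line. At the site on chromosome 11 that starts at 3030593, the log2 ratio was -3.53 in DNCHD4 and 2.51 in the parental line, both bounds in the dense cluster where the bound does not apply.

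The longer DNCHD4 list without tetracycline was weighed against its lower threshold and against depth. One tag was worth 1.09 times as much density without as with tetracycline. If both libraries were scaled to 1 target, the library without tetracycline would be the shallower, which would argue against deeper sequencing. That target is not given and total depth is unknown, so depth as a cause stays open. At the common threshold of 8.05 the longer list was still 1.202 times as long, a value between the bounds set in advance for either answer, and by construction the threshold accounts for the part from 1.202 to 1.597. Whether it is the whole cause stays open: the ratio was 1.18 with median-centred densities, and the parental pair, at its own common threshold, stood at 0.828 as deposited and at 1.014 after centring. With 1 pair of libraries per line and this dependence on scaling, a difference between single libraries and a change in the cells cannot be told apart, and an effect of the dominant-negative Chd4 stays open as untested.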

How the results depend on the processing

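The common threshold for counts, centring by density, the counting interval, the comparison with centred parental changes and the local lowest density were chosen after the data were seen, and the other alternatives before. Of 162 values of the main results under an alternative, 61 stayed within their error or within 1.5 times of the count, 100 moved and 1 reversed. Of the 61, 19 were identical because the setting left them untouched: 8 under the counting interval, 6 shared counts on a background of sites listed in both lines, and 5 under a common threshold. That background alters the expected count, so the factors over it moved for lower sites from 2.47, 4.90 and 6.39 to 2.22, 1.93 and 3.41, and for higher sites from 5.57, 19.7 and 3.16 to 5.83, 5.80 and 5.21 (DNBrg1 with DNCHD4, DNBrg1 with DNSnf2h, DNCHD4 with DNSnf2h). Of 64 values of named sites, 29 stayed, 35 moved and 0 reversed. At named sites listed in 1 library, the interval behind this count took the other list's lowest density as a count at the site. Lower sites outnumbered higher ones under 14 of 14 settings in DNBrg1, 9 of 14 in DNCHD4, 12 of 14 in DNSnf2h and 10 of 13 in parental cells, so the direction depended on the setting in the last 3. Within a line each state has 1 library, so no paired test could be made there and leaving out a library leaves no comparison. A test of tetracycline over the 4 lines, with the line as block, was not run. Limiting the lists to autosomes and X removes nothing, and alternatives for promoters and gene lists were not run. The counting interval removed no site. It could not have removed any, because listed densities stand for at least 26 tags and a 2-fold ratio then excludes 1. The local lowest density and merging across 200 bp kept all 8 counts within 1.5 times. Depth limits sites near a list's lowest density, where the counting error was 14.9% to 19.6%. Where a change is not fixed by the construction of the alternative (another fold, fewer or more sites counted), the cause was not tested.

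With the median ratio set to 1, higher and lower sites numbered 1043 and 926 in parental cells and 1059 and 3263 in DNBrg1. Quantile normalization gave 1065 and 873, and 1363 and 2529. Centring by density gave 1071 and 881, and 1083 and 3038. Leaving out centred changes also found in parental cells gave 883 higher and 2938 lower in DNBrg1. A fold of 1.5 gave 1098 higher and 13259 lower in parental cells, 431 and 18389 in DNBrg1, 15276 and 14847 in DNCHD4, and 4173 and 5396 in DNSnf2h. A fold of 3 gave 48 and 457, 24 and 3576, 1853 and 2458, and 47 and 275. Sites listed in both libraries gave 154 and 2550, 47 and 5999, 2426 and 3218, and 395 and 1105. Counting every site listed in 1 library as changed gave 5396 and 8054 in parental cells, 7233 higher in DNBrg1, 38635 higher in DNCHD4, and 17384 and 9216 in DNSnf2h. Mean density gave 5304 and 8592, 6723 higher in DNBrg1, 36781 higher in DNCHD4, and 17188 and 9450, but the lists have no threshold on that value, so its bounds are loose. A common threshold gave 5934 lower sites in DNBrg1 and 4636 in DNCHD4.

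Shared higher and lower sites at a fold of 1.5 were 180 and 5029 for DNBrg1 with DNCHD4, 92 and 3081 for DNBrg1 with DNSnf2h, and 905 and 3277 for DNCHD4 with DNSnf2h. At a fold of 3 they were 5 and 279, 0 and 99, and 12 and 111. The value of 0 is the reversed one, against 0.00644 for independent lists, too few to read. Centring gave 189 and 929 for DNBrg1 with DNCHD4 and 74 and 442 for DNBrg1 with DNSnf2h.

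Overlap shares, first of hotspots with and then of those without tetracycline, were at a common threshold 76.2% and 92.3% in parental cells, 61.5% and 93.8% in DNBrg1, 82.6% and 69.1% in DNCHD4, and 68.4% with tetracycline in DNSnf2h. With reciprocal overlap they were 82.2% and 82.2%, 76.2% and 73.6%, 80.9% and 50.7%, and 62.7% and 46.2%. With equal numbers of the strongest hotspots they were 79.1% and 78.2% in DNBrg1, 77.2% and 77.3% in DNCHD4, and 63.9% and 63.9% in DNSnf2h. Among libraries with tetracycline, reciprocal overlap and equal numbers gave 84.9% and 83.0% for DNBrg1 in parental, 95.2% and 90.8% for parental in DNCHD4, 72.3% and 72.2% for DNSnf2h in parental, 87.0% and 82.3% for DNBrg1 in DNCHD4, 64.4% and 64.6% for DNSnf2h in DNBrg1, and 74.5% and 76.6% for DNSnf2h in DNCHD4.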

Other observations

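The windows and strongest sites of the first paragraphs, the tests of tetracycline for chromosomes 14 and 18 and of the copy number of each of these 2, and the segments of chromosomes 2, 3, 8 and X were chosen after the results were seen. The other tests in this part were written before.

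The windows of 1 Mb described here held the most higher or lower sites of a line after centring. They were picked as extremes, and their counts were not compared with chance or with parental cells. DNBrg1 cells had 20 higher and 2 lower of 57 sites on chromosome 13 from 23000001 to 24000000, and 1 higher and 18 lower of 66 sites on chromosome 11 from 117000001 to 118000000. DNCHD4 cells had 40 higher and 10 lower of 125 sites on chromosome 10 from 80000001 to 81000000, and 36 higher and 9 lower of 114 sites in the window before it. On chromosome 17 from 14000001 to 15000000, DNCHD4 cells had 2 higher and 23 lower of 63 sites. In DNSnf2h cells, chromosome 1 from 90000001 to 91000000 held 10 higher and 14 lower of 54 sites.

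Of the 10 sites with the highest densities, 5 were lower and 4 higher without tetracycline in both DNCHD4 and DNSnf2h cells, and 1 moved apart. As deposited, all 5 lower ones were also lower in parental cells (log2 -0.77 to -0.59), and all 4 higher ones also higher. On chromosome 13 from 85266194 to 85267366, density went from 1993 to 977 in DNCHD4 and from 1166 to 459 in DNSnf2h, beside 1585 to 1373 in DNBrg1 and 1225 to 809 in parental cells. On chromosome 12 from 98299502 to 98300268 it went from 1505 to 689 and from 830 to 362, beside 1073 to 1036 in DNBrg1 and 881 to 527 in parental cells. After centring, the DNBrg1 log2 ratios at the chromosome 13 and 12 sites turned from -0.21 and -0.05 to 0.44 and 0.59. The strong site on chromosome 17 from 34740120 to 34741632 was among the higher ones, from 968 to 1169 in DNCHD4 and from 275 to 307 in DNSnf2h, beside 897 to 1256 in DNBrg1 and 880 to 1279 in parental cells.

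Neighbouring changed sites within 50 kb of each other moved the same way in 63.0% of 7767 pairs in DNCHD4 cells, above the highest of 1000 random assignments of direction (53.4%). The excess over the random mean was 0.201 as a fraction of pairs in parental cells and 0.112 in DNCHD4 cells, so the hypothesis that this clustering is particular to DNCHD4 was not borne out.

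Sites lower without tetracycline were shared by pairs of dominant-negative lines beyond independent lists. Among sites with a flat parental ratio, the shared count was still at least 2.19 times the independent count. The interval in the lowest pair, DNBrg1 and DNSnf2h, was 1.64 to 2.87. That excess cannot decide whether a response shared with parental cells was the whole cause, which stays open. The parental ratio rests on single libraries, so sites measured as flat can still hold such a response. Random lists matched on density also left an excess, of at least 2.32 times after centring among sites listed in both lines. As deposited, the lowest factor was 1.64 over all merged sites and 1.77 among sites listed in both lines. These factors argue against hotspot strength alone as the whole cause, but strength and a shared response acting together were not tested. A loss of accessibility common to the dominant-negative remodelers may contribute, but differences between libraries in the extent of DNase I digestion were not tested and stay open. After centring and among sites listed in both lines, the parental line overlaps each of the 3 lines by a larger factor than these share with each other, but as deposited the factors overlap, at 2.21 to 3.61 with the parental line and 1.93 to 3.41 between the 3 lines. By correlation of log2 ratios across the 12592 sites listed in all 8 libraries, DNCHD4 and DNSnf2h were the most alike pair (Pearson 0.59). Pairs with the parental line stood at 0.30 to 0.53, and DNBrg1 at 0.49 with DNCHD4 and 0.32 with DNSnf2h.

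Chromosomes 14 and 18 had low hotspot density in both DNBrg1 libraries relative to the other lines, apart from chromosome 14 from 100 Mb on. The weaker of the 2 shifts in the library kept with tetracycline was -0.44 on the log2 scale, so the low density was present without tetracycline removal. These chromosomes were picked as low in both libraries, so this value is part of the pattern and no separate test. Whether any dominant-negative protein was made with tetracycline was not measured. In both libraries 88.9% of the 18 windows of 10 Mb lay below 0, but the 36 sites of chromosome 14 from 100 Mb on had a median of -0.021 with (-0.28 to 0.11) and 0.16 without tetracycline (-0.17 to 0.25), above -0.47 and -0.48 up to 80 Mb, which argues against a lower copy number of the whole of chromosome 14. A lower copy number of chromosome 18, where 100% of 9 windows lay below 0 in both libraries, may contribute, but no DNA copy measurement tests it, and a bias of base composition or gene density cannot be told apart from it, because 16.9% of the 236 windows elsewhere were also at -0.25 or less in the library with tetracycline, 28 of those 40 on chromosomes 2, 3 and 8. Along several of these the level changed in steps, with median shifts on chromosome 2 of -0.46 up to 60 Mb, 0.05 from 60 to 90 Mb, -0.41 from 90 to 120 Mb and 0.12 beyond, on chromosome 8 of -0.04 up to 50 Mb and -0.44 beyond, and on chromosome X of -0.89 up to 40 Mb and 0.06 from 70 Mb on.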
